A study of Homo sapiens with 4 samples.

How the data were processed

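The study measured messenger RNA by RNA-seq in 4 libraries of THP-1 cells. Per the labels' protocols, cells were grown in RPMI1640 with 10% serum at 37 °C and 5% CO2, RNA was extracted with a column kit, and 1.3 µg of total RNA per library went into a SMARTER mRNA-seq kit. Groups and siRNA numbers were taken from the sample titles and matched to the columns of the table by those titles. Both siRNA libraries carry the same genotype and treatment labels and were treated as 2 samples of 1 group, so their spread includes differences between the siRNAs. As they carry different siRNAs, these 2 samples came from separate transfections. The labels do not say whether the cultures were otherwise independent, so p-values measure only the spread between these samples.

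The authors deposited 1 table of normalized counts per gene symbol, used here as a signal that is never negative. Per the submitters' processing notes, kallisto 0.46.2 and GRCh38 were used. The normalization formula and the strandedness of the counting are not given in the sources used here. All 4 columns were used and the number of other columns was 0. The column totals lie close together, so they do not show depth. Depth was estimated from the spacing of low values, which are multiples of what 1 read is worth where whole reads were counted: between 66.9% and 71.9% of low values per library were whole multiples within 0.05 of a read. That is too few to recover the reads, so no count test was run across genes; approximate reads served for depth, floors and the counting intervals of a few genes near 0. A floor of 3 reads corresponds to 2.78 normalized counts in the normoxic library, 3.65 in the hypoxic control, 2.35 with siRNA 1 and 3.39 with siRNA 2. Intervals and floors cover counting error only. EEF1A1 took the largest share of each library, from 2.04% to 2.32%, and mitochondrially encoded genes took 4.29% in normoxia, 4.90% in the hypoxic control, 4.83% with siRNA 1 and 5.30% with siRNA 2.

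All differences are on the scale of log2(normalized count + 1), which understates the change of low genes. Genes with a mean over the 4 libraries of at least 20 were kept, 10805 of the 28546 symbols above 0 in any library. Hypoxia was compared between the 2 control siRNA libraries by a fixed rule of 2-fold, without a test. SREBP2 siRNA was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on all 4 libraries in 3 groups, with 1 residual degree of freedom and a prior of 11.4 degrees of freedom, and a two-sided Benjamini-Hochberg adjusted p under 0.05. The single libraries are assumed to vary like the siRNA pair. The same test was run on simulated data with 200 changed genes among 10805. It called 38 of 50 genes with a true log2 change of 1, 25 of 50 with -1, 50 of 50 with 2 and 41 of 50 with -2, and 13 of 10605 unchanged genes. Simulated genes of like expression shared 1 spread, and both siRNAs had the same effect. Real genes and siRNAs differ in these respects, so these shares do not give the power of the test here.

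There were 23 gene lists fixed before the data were examined: cholesterol synthesis, SREBP regulation and sterol uptake, fatty acid synthesis, LXR targets, HIF targets, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded genes, inflammatory cytokines and NF-kB targets, interferon response, adhesion and migration, proliferation, integrated stress response, endoplasmic reticulum chaperones, p53 targets, NRF2 targets, monocyte identity, macrophage differentiation, markers of other cell types, ribosomal proteins, replication-dependent histones, immediate early genes and common reference genes. Some genes belong to more than 1 list. The list gene RIGI was found under its older symbol DDX58. The median of each list was placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of these libraries. Because the hypoxic control is shared, 200 simulations drew noise from the difference between the siRNA libraries for genes of like expression, with no effect or with the hypoxia differences only, shrunk for noise. Both directions of the shared-library shares and the correlations were read against these simulations.

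Genes named in the text had a mean of at least 50 and were, by a rule fixed before the data were examined, the 10 highest and 10 lowest for hypoxia, the 10 highest and 10 lowest for SREBP2 siRNA by the lesser change of the 2 siRNAs among limma calls (filled up without the threshold where fewer passed), the 5 highest and 5 lowest between the siRNAs, and up to 4 tested members of each list per comparison, those farthest from 0, without the minimum of 50. Loci without a gene name were passed over by the rule. Some genes that the rule names are not reported here; they stay in the counts and list medians. Coordinates are 1-based from GENCODE 29, on GRCh38, the build in the submitters' notes, matched by symbol. Transcript GC content was available for 10579 of the 10805 genes (97.9%).

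Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, no filter and a filter of 100, scaling by column total or by the median of ratios, thresholds of 1.5-fold and 3-fold, a limma prior without trend, a robust prior, a minimum change of 1.5-fold (treat), and leaving out either siRNA. Removal of the GC trend from each library (lowess, span 0.3) and a reading without shared libraries were added later. The latter chooses genes that are still 2-fold changed with one siRNA, which leaves out genes that the siRNA brings back, so it does not test the shares. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.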

Results

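THP-1 is an established human monocytic leukaemia line. RNA-seq was done on 4 libraries of THP-1 cells that had been transfected with siRNA for 48 h and then kept for 24 h either in control oxygen or in hypoxia at 1% O2. The libraries fall into 3 groups: control siRNA in normoxia (1 library), control siRNA in hypoxia (1 library) and siRNA against SREBP2 in hypoxia (2 libraries, each with a different siRNA, called siRNA 1 and siRNA 2 here). The series asks whether SREBP2, the transcription factor that switches on cholesterol synthesis and is encoded by SREBF2, regulates the response of monocytes to hypoxia. The values are the authors' normalized counts for 59409 gene symbols, and 10805 genes with a mean of at least 20 were tested. The library totals were 3479537 normalized counts in normoxia, 3508265 in the hypoxic control, 3507972 with siRNA 1 and 3508614 with siRNA 2. From the spacing of low values, 1 read was worth about 0.926, 1.22, 0.784 and 1.13 normalized counts in these libraries, which corresponds to about 3.76e+06, 2.88e+06, 4.47e+06 and 3.10e+06 reads. The hypoxic control, which enters both the hypoxia and the siRNA comparison, was therefore the library with the fewest reads. No library in normoxia received SREBP2 siRNA, so the effect of the siRNA could be read in hypoxia only.

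The siRNA target was lower with both siRNAs. SREBF2 (GRCh38, chromosome 22, 41833079 to 41907308, plus strand) stood at 825 normalized counts in normoxia, 1029 in the hypoxic control, 523 with siRNA 1 and 237 with siRNA 2. The reduction against the hypoxic control was 49.2% with siRNA 1 and 76.9% with siRNA 2, a mean log2 difference of -1.54 ± 0.80 (SD, n = 2). SREBF1, which encodes the related factor SREBP1, stood at 308 in normoxia, 467 in the hypoxic control, 325 with siRNA 1 and 351 with siRNA 2. In limma over all genes neither gene passed (adjusted p = 0.22 for SREBF2 and 0.75 for SREBF1), with 1 residual degree of freedom. SREBF2 passed when only genes with a mean of at least 100 were tested.

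The first comparison asks how hypoxia changed transcript levels in cells with control siRNA. The lists of cholesterol synthesis genes, known targets of the hypoxia-inducible factors (HIF), glycolysis genes and interferon response genes had medians that were higher in the hypoxic than in the normoxic library, each with exceptions among its members. BNIP3, a mitophagy receptor and HIF target, was at 79.0 normalized counts in normoxia and 863 in hypoxia (log2 difference 3.43). HMGCS1, which makes the HMG-CoA used for sterol synthesis, was at 869 and 3603 (2.05), and the glycolytic aldolase ALDOC was at 27.8 and 205 (2.83). In all, 392 genes were at least 2-fold higher and 285 at least 2-fold lower in hypoxia. With noise as large as that between the 2 siRNA libraries and no effect of hypoxia, simulations gave a mean of 142 higher (central 95% 117 to 166) and 141 lower genes (120 to 163). Neither library has a replicate, the difference was read by size and not tested, and part of both counts is expected from noise.

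Of the 19 cholesterol synthesis genes tested, 18 were higher in hypoxia and 14 at least 2-fold higher, with PMVK the exception. The median log2 difference was 1.14, above the medians of all 10000 random lists matched on expression. Mevalonate diphosphate decarboxylase, MVD, was at 106 and 556 (2.38), lanosterol synthase, LSS, at 208 and 897 (2.10), and the acetyl-CoA acetyltransferase ACAT2 at 231 and 798 (1.79). Of the 32 HIF targets tested, 29 were higher, 16 of them at least 2-fold, and 1 was at least 2-fold lower, with a median of 0.96. Beside BNIP3 the largest differences were in PFKFB4, which controls glycolytic flux (2.42), TMEM45A (2.11) and the transcriptional repressor BHLHE40 (1.48). Of the 21 glycolysis and lactate export genes, 18 were higher and 9 at least 2-fold higher, with a median of 0.84. These included the enolase ENO2 (1.75) and the glucose transporter SLC2A1 (1.64), while the phosphofructokinase PFKM was lower (-1.44). The medians of the HIF and glycolysis lists also lay above those of all 10000 random lists.

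The interferon response list had 26 tested genes, of which 22 were higher in hypoxia and 10 at least 2-fold higher, with a median of 0.80. The transcription factor IRF7 was at 5.84 and 36.9 normalized counts (2.47), GBP2 at 21.7 and 82.6 (1.88), the oligoadenylate synthetase OAS1 at 7.08 and 28.2 (1.85) and IFIT3 at 7.69 and 23.2 (1.48). Many of these genes were low, and the median was 0.33 when only genes with a mean of at least 100 were kept. Fatty acid synthesis and desaturation genes had a median of 0.50, with 13 of 18 higher. The acetyl-CoA synthetase ACSS2 was at 101 and 610 (2.59), the desaturase FADS2 at 473 and 1630 (1.78), and fatty acid synthase, FASN, at 1653 and 4364 (1.40), while the acyltransferase GPAM was lower (-1.24). Among regulators of SREBP and sterol uptake the median was 0.30. INSIG1, which retains the SREBP complex in the endoplasmic reticulum, was at 906 and 2539 (1.49), STARD4 was higher by a log2 difference of 0.84 and the protease gene MBTPS2 was lower (-0.98). Nuclear-encoded respiratory chain genes had a median of -0.02, inside the central 95% of random lists, with NDUFB5 the farthest from 0 (-0.99).

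Among the genes named here with a mean of at least 50, the largest hypoxia differences were in the extracellular sulfatase SULF2, BNIP3, the inhibitory receptor CD300A (3.42), TBC1D30 (3.35), ALDOC, the long noncoding RNA LINC02870 (2.67), the sialic acid receptor SIGLEC1 (2.60), ACSS2, the creatine transporter SLC6A8 (2.56) and PFKFB4. SULF2 rested on about 2 reads in normoxia against about 51 in hypoxia, a ratio of 29.3 with a 95% counting interval of 8.81 to 284 (exact Clopper-Pearson). At the other end were the mitochondrial alanine tRNA gene MT-TA (-2.56), the phosphodiesterase gene PDE8A (-2.27), SLC16A14 (-2.23), NEO1 (-2.11), the aldo-keto reductase gene AKR1C2 (at 625 and 155), TANC2 (-1.81), U2AF1L5 (-1.79), ZNF559 (-1.75), the mitochondrial RNA methyltransferase gene NSUN3 (-1.74) and STX17 (-1.71). U2AF1, the near-identical copy of U2AF1L5, was higher, at 300 in normoxia and 456 in the hypoxic control, and the sum of both was at 645 and 555. The 2-fold higher genes had a median transcript GC content of 55.5%, the 2-fold lower genes 44.2% and all tested genes 47.9%. Across genes, which are not independent replicates, the hypoxia difference and GC content had a Spearman rho of 0.33 and a Pearson r of 0.30. For siRNA 1 and siRNA 2 against normoxia rho was 0.21 and 0.19, and against the hypoxic control -0.20 and -0.16. For siRNA 2 minus siRNA 1 it was 0.01. The trend was thus strongest in the hypoxic control, which enters the siRNA comparison too. Markers of other blood, epithelial, stromal and endothelial cell types were near the floor: 16 of 30 were at 0 in all 4 libraries, and only NKG7 passed the filter (30.8 in normoxia, 21.8 in the hypoxic control, 24.5 and 24.7 with the siRNAs).

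The second comparison asks what SREBP2 siRNA changed in hypoxic cells. Most cholesterol synthesis genes were lower with both siRNAs, and more so with siRNA 2, which left less SREBF2. HMGCS1 was at 3603 normalized counts in the hypoxic control, 1460 with siRNA 1 and 311 with siRNA 2 (log2 differences -1.30 and -3.53). FASN fell from 4364 to 2582 and 2425, a mean log2 difference of -0.80 ± 0.06 (SD, n = 2; SE 0.12, limma adjusted p = 0.044). Most interferon response genes were higher with both siRNAs, and more so with siRNA 1.

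**Figure D1:**
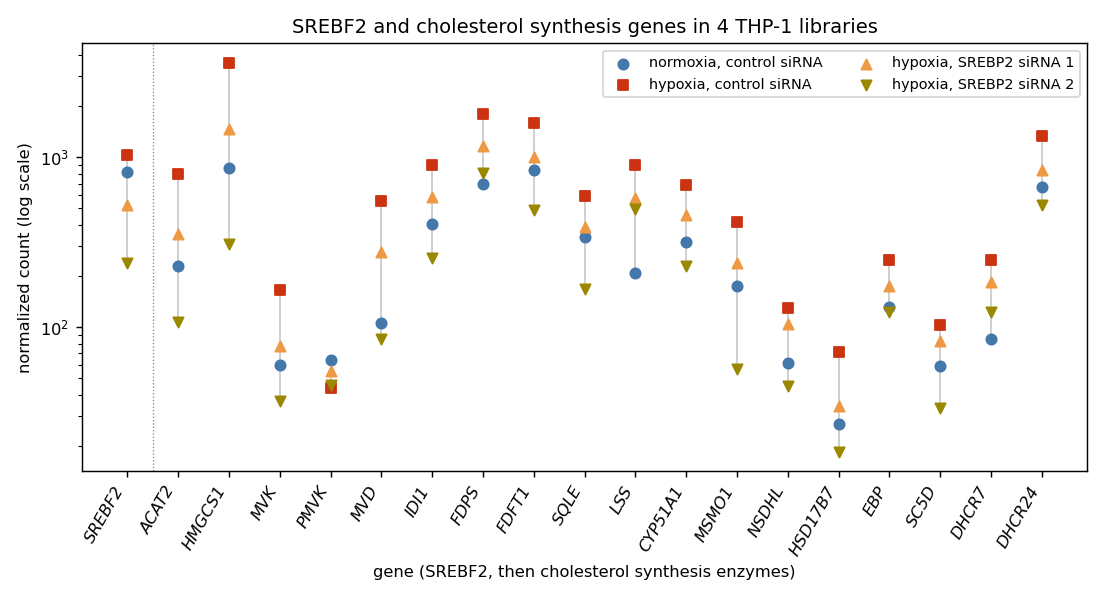
Normalized counts (log scale) of SREBF2 and 18 cholesterol synthesis genes, 1 point per library. In 17 of these 18 genes both siRNA libraries lie below the hypoxic control; PMVK is the exception, and HMGCS1 runs from 3603 in the hypoxic control to 311 with siRNA 2.

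Of the 19 cholesterol synthesis genes, 18 were lower with both siRNAs, 5 at least 2-fold with siRNA 1 and 17 at least 2-fold with siRNA 2. The list median was -0.64 with siRNA 1 and -1.70 with siRNA 2, each below all 10000 random lists, and -1.18 for the mean of both. ACAT2 went from 798 to 355 and 108 (-1.17 and -2.88), MVD from 556 to 277 and 85.0 (-2.70 with siRNA 2), and the methyl sterol oxidase MSMO1 from 419 to 238 and 56.6 (-0.81 and -2.86). In limma, 0 members passed over all genes tested, 16 were lower adjusted over the list alone, and 17 were lower at an unadjusted p under 0.05. The spread between the siRNAs entered the error, with an SD of 1.58 for HMGCS1. With only genes of a mean of at least 100 tested, 11 of 14 members passed over all 6407 genes, HMGCS1 and ACAT2 among them.

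Fatty acid genes were lower by less, with list medians of -0.23 and -0.34. FASN (chromosome 17, 82078333 to 82098332) was the member that passed over all genes, and 5 members were lower adjusted over the list alone. ACSS2 was at 299 and 267 against 610 (-1.02 and -1.19, limma adjusted p = 0.15), PNPLA3 at 79.6 and 72.1 against 136, and ATP citrate lyase, ACLY, at 1654 and 1192 against 2101. With only genes of a mean of at least 100 tested, 2 of 16 members passed, ACSS2 and FASN. Regulators of SREBP and sterol uptake, a list that holds SREBF2 itself, had medians of -0.12 and -0.20. In it, 0 members passed over all genes, 2 were lower adjusted over the list alone, and at an unadjusted p under 0.05 there were 5 lower and 1 higher. TMEM97 was lower (-0.55 and -2.13), and INSIG1 was at 1944 and 1418 against 2539. The sterol acyltransferase gene SOAT1 was higher (0.45 and 1.03), as was ERLIN2 (0.23 and 1.17).

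Interferon response genes had medians of 1.12 with siRNA 1 and 0.41 with siRNA 2, and 22 of 26 were higher with both. The antiviral GTPase MX1 was at 16.4 normalized counts in the hypoxic control, 137 with siRNA 1 and 37.4 with siRNA 2 (2.99 and 1.14). IFIT1 was at 8.52, 47.0 and 21.5 (2.33 and 1.24), IFIT3 at 23.2, 114 and 44.9 (2.25 and 0.92), and USP18 at 13.4, 71.6 and 22.5 (2.34 and 0.71). In the hypoxic control 1 read was worth about 1.22. The values of IFIT1, USP18 and MX1 there thus rest on few reads, and the sizes of their differences are imprecise. MX1 and USP18 had been lower in hypoxia than in normoxia, where they were at 30.5 and 24.2 (-0.85 and -0.81), and GBP2, which was higher in hypoxia, was lower with both siRNAs (-1.36 and -0.41). In limma, 0 members passed over all genes, 7 were higher adjusted over the list alone, and 12 were higher at an unadjusted p under 0.05. With only genes of a mean of at least 100 tested, 2 of 9 members passed, XAF1 among them.

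Over all 10805 genes limma called 5 higher and 2 lower with SREBP2 siRNA, and 361 higher and 330 lower at an unadjusted p under 0.05. MEF2C, a transcription factor gene (chromosome 5, 88717117 to 88904257), rose from 179 to 449 and 414, a log2 difference of 1.27 ± 0.08 (SD, n = 2; SE 0.20, adjusted p = 0.044). MT-TA (mitochondrial genome, 5587 to 5655) rose from 11 to 118 and 102 (3.21 ± 0.15, adjusted p = 0.0031), with a normoxic level of 69.7. U2AF1L5 (chromosome 21, 6484623 to 6499261) rose from 98.9 to 354 and 294 (1.70 ± 0.19, adjusted p = 0.014), with a normoxic level of 345, and FAM156A (chromosome X, 52926402 to 52995472) rose from 17.2 to 98.1 and 115 (2.56 ± 0.16, adjusted p = 0.033). In normoxia MEF2C was at 252 and FAM156A at 26.5. The remaining higher call, named after its values were seen, was the antisense transcript AC116366.1 (chromosome 5, 132468890 to 132473043). It was at 0 in the hypoxic control but at 39.6 in normoxia, 44.8 with siRNA 1 and 64.6 with siRNA 2. The siRNA values were 12.3-fold and 17.7-fold a floor of 3 reads in the control. The 95% counting intervals of the ratios to the control began at 9.64 and 13.9. The strandedness of the counting is not given, so reads of this antisense transcript cannot be told apart from those of a gene on the other strand. MT-TA encodes a short tRNA, and FAM156A and U2AF1L5 have near-identical copies that can take their reads. All 7 calls ended without the filter on low values or with a prior without an intensity trend, at 3186 and 679 genes with an unadjusted p under 0.05.

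Genes next in size did not pass over all genes tested. With only genes of a mean of at least 100 tested, EHMT1, INO80, PLEKHA3, HMGCS1 and ACAT2 among them passed. Among those higher were ZDHHC2 (1.55 and 1.62), C15orf40 (1.31 and 1.62), the read-through locus MSH5-SAPCD1 (1.27 and 1.41), TFB1M (1.29 and 1.26), PLEKHA3 (1.23 and 1.47) and the mitochondrial asparagine tRNA gene MT-TN (1.24 and 1.20). Among those lower were FAM156B, LINC01002 (-1.46 and -1.89), ANKMY1 (-1.32 and -1.52), HMGCS1, the histone methyltransferase gene EHMT1 (-1.30 and -1.96), ACAT2, the chromatin remodeller gene INO80 (-1.16 and -1.35) and mevalonate kinase, MVK (-1.09 and -2.15). The hypoxic control was below normoxia in all of these higher genes and above it in all of these lower genes. ZDHHC2 was at 99.1 in normoxia, 30.5 in the hypoxic control, 91.1 with siRNA 1 and 95.8 with siRNA 2. LINC01002 was at 36.9, 109, 38.9 and 28.6. FAM156B, at 124 in normoxia, was below both controls with each siRNA. With 1 hypoxic control library, an odd reading of it cannot be told apart from an siRNA effect in genes such as ZDHHC2. By size alone, 63 genes were at least 2-fold higher and 48 at least 2-fold lower with both siRNAs. Because both siRNAs share the control library, no effect at all gave 37.5 (central 95% 28 to 48) and 37.2 (26.0 to 47) in simulations, and independent lists would share 3.13 and 2.5 genes. Both observed counts lay above the simulated ranges, the count of lower genes by 1 gene. With the GC trend removed, an alternative chosen after seeing the data, 55 genes were higher (simulated 23 to 45.1) and 47 lower, inside the simulated 24 to 47.0. The simulated noise is that of the siRNA pair, and the noise of the shallower single control is not known.

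The third comparison asks how far the hypoxic libraries lay from the normoxic control. Without SREBP2 siRNA in normoxia, a changed response to hypoxia cannot be told apart from an siRNA effect that is also present in normoxia. The median of the cholesterol list was smaller with both siRNAs, while that of the HIF list was larger with both and that of the glycolysis list differed little. Against normoxia, the median of the cholesterol list was 1.14 in the hypoxic control, 0.49 with siRNA 1 and -0.52 with siRNA 2. The median of the HIF list was 0.96, 1.16 and 1.22, and that of the glycolysis list 0.84, 0.91 and 0.79. The fatty acid list went from 0.50 to 0.06 and 0.02, and the interferon list from 0.80 to 1.52 and 0.98. All 14 cholesterol genes that were at least 2-fold higher in hypoxia were lower with both siRNAs, 5 of them at least 2-fold. Of the 16 HIF targets at least 2-fold higher in hypoxia, 3 were lower with both siRNAs and 0 by 2-fold, and of the 9 such glycolysis genes 2 were lower with both and 0 by 2-fold. Such genes are chosen and read on the same hypoxic control, so many would be lower with no siRNA effect. Of all 392 genes at least 2-fold higher in hypoxia, 57.7% were lower with both siRNAs. Simulations with the hypoxia differences and no siRNA effect gave 63.0%. The differences between lists were not tested.

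**Figure D2:**
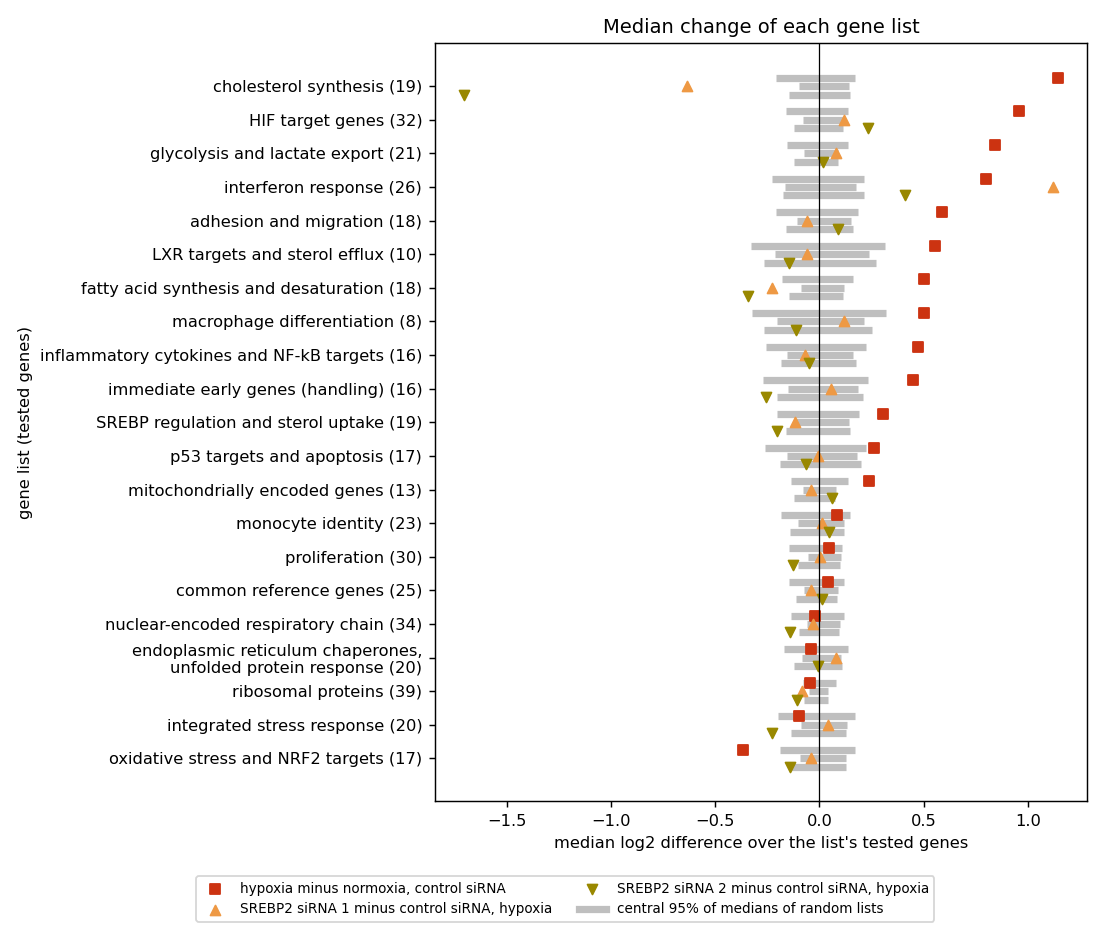
Median log2 difference of each gene list for hypoxia against normoxia (squares) and for each SREBP2 siRNA against control siRNA in hypoxia (triangles), with the central 95% of medians of random lists in grey and the number of tested genes in brackets. The cholesterol list is at 1.14 for hypoxia and at -0.64 and -1.70 for the siRNAs, while the HIF list is at 0.96, 0.12 and 0.24.

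Within the HIF list 21 of 32 genes were higher with both siRNAs and 3 lower. The list medians were 0.12 with siRNA 1 and 0.24 with siRNA 2, above the central 95% of random lists, at the 98.1 and 99.99 percentiles. NDRG1 was at 300 in the hypoxic control and at 455 and 571 with the siRNAs, the kinase gene PDK1 at 266, 414 and 355, TMEM45A at 176, 252 and 256, and FAM162A at 127, 170 and 182. VEGFA, named after its values were seen, was at 265 in normoxia, 441 in the hypoxic control, 469 with siRNA 1 and 474 with siRNA 2. In limma 0 HIF targets passed over all genes or adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. Glycolysis genes had siRNA medians of 0.08 and 0.02, with ALDOC lower (-0.52 and -0.74), SLC2A3 higher (0.45 and 0.30) and HK3 higher (0.31 and 0.48). In that list 0 passed over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05.

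Over all genes, 226 of the 392 genes higher in hypoxia (57.7%) were lower with both siRNAs, and 233 of the 285 genes lower in hypoxia (81.8%) were higher with both. The hypoxic control enters both differences with opposite sign, so such shares arise by chance. Simulations with the hypoxia differences and no siRNA effect gave 63.0% (central 95% 57.7 to 68.1) and 68.1% (63.2 to 73.9). With no hypoxia effect either, they gave 78.2% (71.8 to 84.6) and 78.3% (70.6 to 85.2). Across genes the hypoxia and mean siRNA differences had r = -0.49 against -0.44 (-0.47 to -0.42) in the simulations with the hypoxia differences, and a covariance of -0.102 against -0.083 (-0.091 to -0.077), both outside the simulated ranges. With the GC trend removed, r was -0.46 against -0.46 and the covariance, -0.091, lay inside the simulated -0.091 to -0.075. All of these simulations take the hypoxic control to be as noisy as the siRNA pair.

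**Figure D3:**
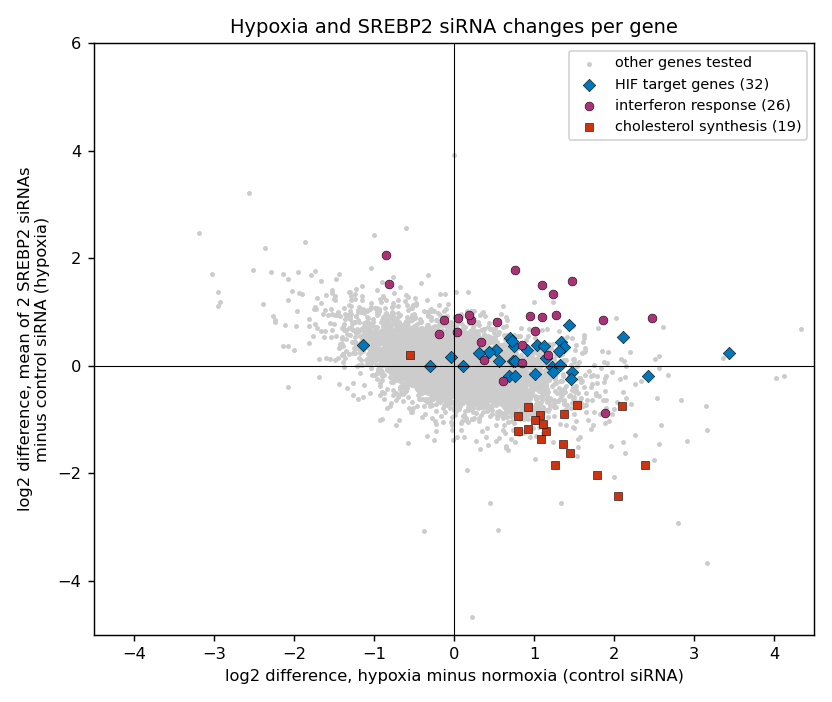
Log2 difference of hypoxia against normoxia (x axis) and of the mean of both SREBP2 siRNAs against control siRNA in hypoxia (y axis), 1 point per gene tested, with 4 genes outside the axes. Cholesterol synthesis genes lie at the lower right, with 18 of 19 higher in hypoxia and lower with both siRNAs, HIF targets at the right near 0 and interferon genes mostly above 0.

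The siRNAs differed from each other in the strength of the changes. Cholesterol synthesis genes were lower with siRNA 2 than with siRNA 1 in 19 of 19 cases, with a median log2 difference of -1.04, led by HMGCS1 (-2.23) and MSMO1 (-2.05). Interferon genes were lower with siRNA 2 than with siRNA 1 in 23 of 26 cases (median -0.59), led by MX1 (-1.85). Both medians lay below all 10000 random lists. Other genes far apart were FAM156B (-2.82) and TMEM19 (-1.99), and, higher with siRNA 2, ARL11 (2.14), TRIM66 (1.95), SIPA1L3 (1.80), MBD5 (1.63) and ZNF346 (1.62). With 1 library per siRNA, these differences were not tested. The changes with the 2 siRNAs against the shared control had r = 0.55 across genes against 0.50 in simulations with no effect. The covariance was 0.10 against 0.08, and both lay above the simulated ranges (0.47 to 0.52 and 0.077 to 0.090). The simulations gave the shared control the noise of the siRNA pair. More noise in that control alone would raise both values, so the excess does not show an effect that both siRNAs share.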

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

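The GC-trend removal and the readings without a shared library were chosen after the results were seen; the other alternatives were planned. Of the values for counts, shares and the main lists, 97 stayed within their limits and 49 did not; scaling by total or by median of ratios moved none of the latter, and no scaling moved the all-gene median by more than 0.035 from 0. Without the filter on low values the hypoxia counts went from 392 higher and 285 lower to 4346 and 2442, the counts with both siRNAs from 63 and 48 to 1152 and 2038, the limma calls from 5 and 2 to 0 and 0, and the shares from 57.7% and 81.8% to 74.0% and 54.9%; more genes of a few reads were then tested. At a filter of 100 these counts were 134 and 50, 5 and 11, and 9 and 26, with 4 of the 7 calls among the 35. The remaining calls, AC116366.1, MT-TA and FAM156A, had means under 100 and were not tested there. A pseudocount of 8 gave 179 genes lower in hypoxia, 29 higher and 27 lower with both siRNAs. Thresholds of 1.5-fold and 3-fold gave 1190 and 103 genes higher and 1059 and 52 lower in hypoxia, and 290 and 9 higher and 258 and 6 lower with both siRNAs. The limma calls were 0 and 0 with a prior without trend, 2 and 0 with treat, 1 lower with a robust prior and 13 lower with the GC trend removed. Leaving out either siRNA gave 156 to 217 genes higher, 133 to 203 lower, and shares of 63.8% to 76.0% and 87.4% to 92.3%, as a single siRNA has to meet the rule; limma then has no residual degree of freedom and gives no test. Without a shared library the shares were 34.2% and 50.1%, and 53.7% and 46.3%, but that choice leaves out genes that the siRNA brings back to the normoxic level and reads 1 siRNA, so it does not test the shares. The hypoxia medians became 1.26 (cholesterol) and 0.77 (glycolysis) with the GC trend removed, 1.08 (HIF) without the filter, and for interferon 0.56 with a pseudocount of 8, 0.57 without the filter and 0.33 at a filter of 100; the cause was not tested. The siRNA median of the integrated stress response changed sign without replicate 2 (0.041, and -0.23 without replicate 1, against -0.12). No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Depth limits genes of a few reads most in the hypoxic control, where 3 reads are 3.65 normalized counts.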

Other observations

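The tests on the interferon genes, the random-list test of the cholesterol genes and the GC correction were chosen after the results were seen. Adhesion and migration genes were higher in hypoxia, with 15 of 18 higher and a median log2 difference of 0.59, above all 10000 random lists. The proteoglycan gene VCAN was at 5.14 in normoxia and 53.3 in the hypoxic control (3.14), the integrin gene ITGAL at 46.0 and 120 (1.37), the chemokine receptor gene CXCR4 at 177 and 418 (1.23) and CX3CR1 at 30.5 and 70.7 (1.19). With the siRNAs this list had medians of -0.06 and 0.09, with ITGAM higher (9.19 in the control, 50.2 and 20.1), ITGAX higher (0.44 and 0.59) and VCAN lower (-0.68 and -0.81). Inflammatory cytokines and NF-kB targets were higher in hypoxia in 13 of 16 cases (median 0.47). TNF was at 98.5 and 234 (1.24), CXCL8 at 36.0 and 72.6 (0.99), the inhibitor gene NFKBIA at 61.9 and 123 (0.99) and IL1RN at 38.4 and 72.4 (0.90), and the siRNA medians were -0.07 and -0.05. The alarmin genes S100A8 and S100A9 were higher with siRNA 2 (1.08 and 0.78) but not with siRNA 1 (-0.16 and -0.05). NRF2 targets were lower in hypoxia in 14 of 17 cases (median -0.37, with 1 of 10000 random lists as low). They included the cystine transporter gene SLC7A11, at 967 and 449 (-1.11), the glutathione synthesis gene GCLC (-0.73), ME1 (-0.62) and TXNRD1 (-0.53), and the siRNA medians were -0.04 and -0.14. Of 24 macrophage differentiation markers only 8 passed the filter, and MRC1, C1QA and FABP4 were at 0 in all 4 libraries. Among the 8 tested, 6 were higher in hypoxia and 2 lower (median 0.50). TREM2 (0.87), GPNMB (0.87) and CD68 (0.61) were higher, and LPL was lower (117 and 86.6). Monocyte identity genes had a median of 0.09, with CSF1R (1.00) higher. The siRNA medians were 0.12 and -0.11 for the macrophage list, and 0.01 and 0.04 for the monocyte list.

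LXR targets and sterol efflux genes had a hypoxia median of 0.56, with the lipid droplet gene PLIN2 at 259 and 649 (1.32) and the cholesterol exporter gene ABCA1 at 53 and 18.4 (-1.48). Their siRNA medians were -0.06 and -0.15, with ABCA1 higher (0.60 and 0.50) and NR1H2 lower (-0.87 and -0.37). The immediate early list had 0.45 in hypoxia, led by BTG2 (1.97) and JUN (1.15), and 0.06 and -0.26 with the siRNAs. The p53 list had 0.26, led by CDKN1A (195 and 629, 1.69) and TP53INP1 (1.04), and -0.01 and -0.07 with the siRNAs. Mitochondrially encoded genes had 0.24 in hypoxia, with MT-CO3 at 0.46, and -0.04 and 0.06 with the siRNAs. Proliferation genes had 0.05, then 0.00 and -0.13, with TK1 higher in hypoxia (0.83) and AURKB lower with the siRNAs (-0.31 and -0.74). The integrated stress response list had -0.10, then 0.04 and -0.23, with ASNS lower in hypoxia (-0.87) and CHAC1 lower with the siRNAs (-0.44 and -1.02). Endoplasmic reticulum chaperones had -0.04, then 0.08 and -0.01, with ERN1 lower in hypoxia (-1.01) and higher with the siRNAs (0.61 and 0.61). Respiratory chain genes had siRNA medians of -0.03 and -0.14. Ribosomal protein genes had -0.04 in hypoxia, inside the central 95% of random lists, and -0.08 and -0.11 with the siRNAs, small values but below nearly all random lists, with 29 of 39 lower with both. Common reference genes had 0.04, then -0.04 and 0.01, yet PGK1 (1.14), POLR2A (1.00), GPI (0.98) and GAPDH (0.56) were higher in hypoxia. Of 35 histone genes only H1-2 passed the filter, at 30.9 in normoxia, 54.5 in the hypoxic control and 49.9 and 40.1 with the siRNAs. In limma, 0 genes of any list in these paragraphs passed for SREBP2 siRNA, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 3 in the adhesion list, 1 each in the chaperone, NRF2 and ribosomal lists, 2 in the reference list and 0 in the others.

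Many genes that differed in hypoxia differed in the opposite direction with SREBP2 siRNA, and the cholesterol list is the clearest case. For genes higher in hypoxia there was no excess over noise of the shared hypoxic control, since the observed 57.7% lay just below the simulated range, which ended at 68.1%, and 55.8% below 59.2% to 69.8% with the GC trend removed. For genes lower in hypoxia the observed 81.8% exceeds the simulated upper end of 73.9%. With the GC trend removed the share was 82.7%. That lies above the simulated 64.1% to 76.0% with the hypoxia differences, but inside the 70.8% to 85.7% with no effect. Removal of the GC trend thus did not lower this share, but whether there is an excess to explain is not settled. The correlation and covariance over all genes had no excess after that removal. Shared noise cannot be told apart from an effect. The bound of 73.9% was set wrongly, as it takes the noise-corrected hypoxia differences as real and the control to be as noisy as the siRNA pair, and with no real hypoxia difference the simulated upper end was 85.2%. For cholesterol synthesis genes, noise that is independent between genes and GC bias are argued against as the whole cause. The highest of 10000 random hypoxia medians was 0.38 against 1.14 observed, and the siRNA median was -1.19 with the GC trend removed. Random lists cannot show a joint shift of these genes in the single hypoxic control library. Such a shift would also place the list higher in hypoxia and lower with both siRNAs. A hypothesis is that these genes were higher in hypoxia through SREBP2, which a replicated design with siRNA in normoxia could test.

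The interferon list had a higher median in hypoxia and higher ones again with both siRNAs, with 18 of 26 genes higher in all 3 differences, 4 lower in hypoxia but higher with both siRNAs, and GBP2 the other way round. Noise of the hypoxic control would move them in opposite directions in the 2 comparisons, and the lowest of the 3 medians was 0.41, above the central range of random lists, which argues against that noise. A response in proportion to the loss of SREBF2 would be larger with siRNA 2, but the median of siRNA 2 minus siRNA 1 was -0.59. With 1 library per siRNA this stays open, as a response to an siRNA duplex itself could differ by sequence. Lower sterol synthesis has been linked to interferon signalling in macrophages, so a biological source also remains possible and untested here.

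Among the limma calls were members of near-identical gene pairs that moved apart. FAM156A rose while FAM156B was lower (145 in the control, 14.2 with siRNA 1 and about 1 read with siRNA 2, a ratio of 126 with a 95% counting interval of 22.5 to 5095), and their summed value changed by -0.50 ± 0.04 (SD, n = 2). U2AF1L5 rose while U2AF1 went from 456 to 332 and 337, and their sum changed by 0.25 ± 0.08. Both sums moved by less than the single genes. The sum of any 2 genes that move apart changes by less than the larger single change. The sums therefore cannot decide whether reads were assigned to one or the other copy. No biological explanation was tested for these pairs.

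The 364 tested genes with ZNF symbols had a hypoxia median of -0.094, at the 0.80 percentile of random lists, and -0.048 with the GC trend removed, at the 7.79 percentile and inside the central 95% of random lists.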
